A study of Mus musculus with 61 samples.

How the data were processed

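Adipose RNA from 61 mice of the 8 founder strains had been made into mRNA libraries by poly(A) selection with an added spike-in control and sequenced, per the labels. The authors deposited a table of expected counts for 21169 genes, that is, read estimates in which a read that matches several genes is divided among them. Of these values 21.1% were not whole within 1e-06, and every gene had at least 1 read in at least 30 libraries. The authors also deposited log2 values made from the counts by the variance-stabilising transformation of DESeq2, with no version given. This transformation compresses differences of genes with low counts. Gene positions came from the annotation deposited with the counts, on genome build GRCm38. The aligner and the counting tool are not stated. Symbols that a spreadsheet had turned into dates were restored for 23 genes, and 23 gene identifiers that share a symbol were kept apart.

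Expected counts were rounded. Genes with low counts were removed with filterByExpr by strain, which left 18603 genes and set aside 2566. Of those tested, 4105 (22.1%) had estimates that were not whole in over 50% of libraries, and these are the genes said to share reads. Counts were scaled by TMM and fitted in edgeR 4.0.16 under R 4.3.3 with 1 mean per strain, robust quasi-likelihood dispersion and no covariate. CPM of genes are scaled by TMM with a prior count of 2 where logged. Sums of marker transcripts and Xist are CPM of the library total.

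Strain was tested with an F-test, each strain against the unweighted mean of the other 7, each of 28 pairs, and the 3 wild-derived strains Cast, PWK and WSB against the 5 classical strains 129, AJ, B6, NOD and NZO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over the genes of each contrast. All tests were 2-sided. A ratio from 1 to 3 counts has a 95% interval for counting error.

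Of 721 genes on fixed lists 679 were in the table, and 33 of 34 lists were tested, since the list of male reproductive tract markers kept 1 member. Camera of limma 3.58.1 compared each list with all other genes at a preset correlation of 0.01, adjusted over 297 pairs of list and contrast. Beside it stand camera with an estimated correlation and fry. Random relabelling of libraries showed that camera with the preset correlation calls many lists by chance, and a permutation test was added for that reason. It took the mean log2 CPM of a list per library and permuted all strain labels 100000 times, which tests the absence of any strain difference. The wild-derived contrast was also tested over lists with all 56 splits of the strains into 3 and 5.

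The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. By that rule the text draws, per contrast, on the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM and every library of the strain on the same side of the median of the others (for wild-derived strains, every strain mean on the same side), on the 10 genes with the largest share of variance between strains, on up to 4 members per called list with the member farthest the other way, and on 5 identity genes. Predicted genes, clone names, immune receptor segments, Xist and Y chromosome genes were passed over, and names of 1 or 2 letters with 5 or more digits were added to them after the values were seen. The text gives the genes that matter most of those the rule took.

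Alternatives were RLE size factors, no filter, a filter of at least 5 mean CPM, DESeq2 1.42.0, limma on the variance-stabilised values, the replicate number as a block, 2 surrogate variables from sva 3.50.0, Xist as a covariate, autosomal genes, a doubling or halving, and B6 as the reference. Added after the data were seen were the fits without libraries rich in liver (7 over 500 CPM), genital duct (6 over 300 CPM) or muscle markers (4 over 300 CPM), without Cast replicate 8, without Cast replicates 5 and 6, without NZO replicate 8, without WSB replicate 7, and without genes that share reads, the permutation of list scores, and list differences without named libraries or with Xist. Limits for these libraries were also set after their values were seen.

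The procedure was tested on simulated data with 99 genes changed at each size in NZO. It recovered 69.7% of genes changed by 1 on the log2 scale and 46.5% of those changed by 0.5, and 5.74% of calls fell on unchanged genes. The F-test found 56.6% of genes changed by 1. Camera called a raised list of 20 genes and did not call an unchanged one. Copies of genes near 0 were searched with blastn in GENCODE transcripts at 95% identity over at least 50% of the length. Sex was not inferred from expression, and the spike-in controls are not in the table. Some genes that met the rule for naming are not reported here, and they were left out of the search for outlying libraries after its outcome was seen.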

Results

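RNA from adipose tissue of the 8 founder strains of the Diversity Outbred mouse population was sequenced in 61 libraries. The mice had been placed on a high-fat, high-sugar diet, which the labels give as 45 percent fat. The strains 129, AJ and Cast had 7 libraries each, and B6, NOD, NZO, PWK and WSB had 8 each. Total counts ran from 19851580 in WSB replicate 4 to 61277576 in B6 replicate 8. The labels do not say which fat depot was taken, nor the sex or age of the mice, nor a sequencing batch. The stearoyl-CoA desaturase transcript Scd1, an abundant product of fat cells, took 7.59 ± 2.28% of all counts (SD, n = 61).

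The design implies 1 question, how adipose expression differs among founder strains fed alike. In what follows, a gene is given with its log2 fold change ± standard error, and leading genes also with the adjusted p, with how many of the strain's libraries lay on that side of the median of all other libraries, or with CPM (read counts scaled to library size) as mean ± SD in the strain against the mean of the other strain means. The fold change compares fitted strain means, which 1 library can drive, averaged as logarithms over strains. It can thus differ from the ratio of the CPM means. A gene list is given with its difference in mean log2 CPM over members ± standard error, with libraries counted in the same way, and with 3 p values, each adjusted. The first comes from 100000 permutations of the strain labels, where 6.6e-05 is the smallest adjusted value they gave, from a raw p of 1e-05 that is the smallest possible. The second comes from camera with a preset correlation between genes, and the third, written estimated p, from camera with an estimated correlation. Genes marked "shares reads" have read estimates split with similar genes, and their values are uncertain.

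Strain accounted for much of the expression in these fat samples. Of 18603 genes tested, 16718 (89.87%) differed among the 8 strains in the edgeR F-test. The median gene had 48.7% of its variance in log2 CPM between strains, 8903 genes had over 50% and 1197 had over 80%. Libraries of 1 strain were closer to each other (median r = 0.9595 across genes, which are not independent replicates) than libraries of different strains (median r = 0.9264). On the first principal component, 91.6% of the variance lay between strains, against 33.9% on the second.

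**Figure D1:**
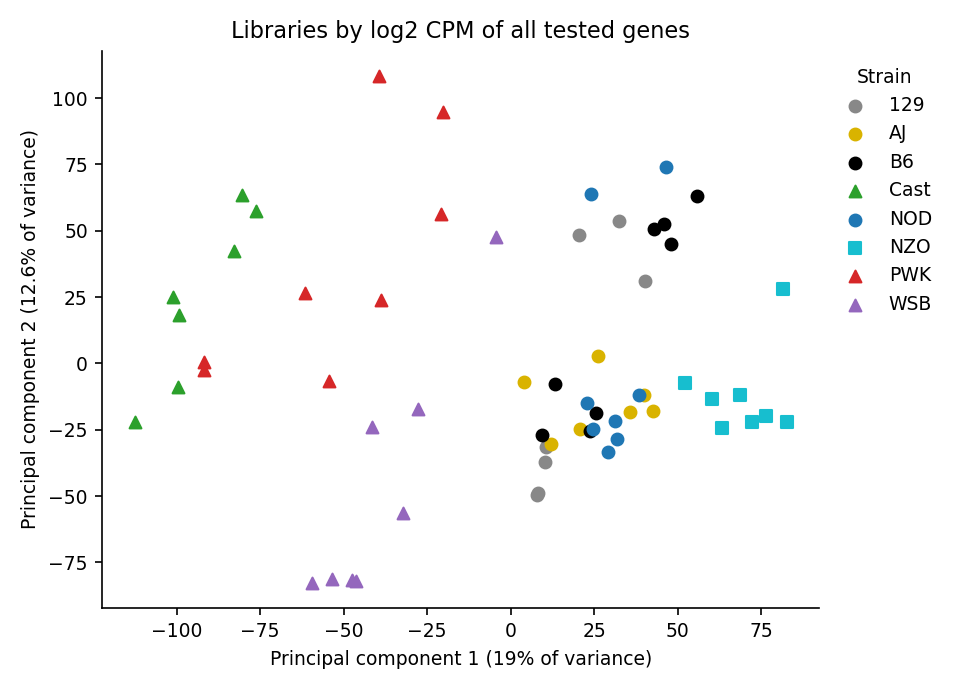
Each point is 1 of the 61 libraries, placed by the first principal component (19% of variance, horizontal axis) and the second (12.6%, vertical axis) of log2 CPM and colored by strain. On the first component Cast, PWK and WSB lie at −112.5 to −4.37, 129, AJ, B6 and NOD at 3.924 to 55.72 and NZO at 52.11 to 82.72, and neighboring strains overlap.

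The 10 genes with the largest share of variance between strains share reads in 8 cases. Zinc finger gene Zfp738 (99.26% of variance between strains, shares reads) ranged from 0.00266 CPM in WSB to 8.77 CPM in B6, and Zfp605 (97.73%) from 0.0514 CPM in PWK to 8.72 CPM in WSB. The splicing factor gene Cwc22 (98.87%, shares reads) had 1120 CPM in WSB and 18.1 CPM in PWK, the lowest strain. Firre (98.17%), a long noncoding RNA gene of the X chromosome (50555744 to 50635321), ranged from 5.51 CPM in PWK to 60.8 CPM in 129. The nonclassical MHC class I gene H2-T22 (98.66%, shares reads) went from 5.36 CPM in NOD to 178 CPM in NZO, and the cytochrome P450 gene Cyp4f16 (97.93%, shares reads) from 0.117 CPM in WSB to 15 CPM in NZO. Rpl17 (98.16%), Rpl27 (98.16%) and Rpl12 (97.96%), which encode ribosomal proteins, and 9930111J21Rik1 (97.64%) all share reads.

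Genes known to carry alleles of particular founder strains served as identity checks. Dysf, which encodes the membrane repair protein dysferlin and carries an insertion in AJ, stood at 7.68 ± 0.91 CPM in AJ (SD, n = 7) against strain means of 63.3 to 119 CPM elsewhere (log2 fold change −3.57 ± 0.126, adjusted p = 4.76e-31 in edgeR). The nicotinamide nucleotide transhydrogenase gene Nnt was lowest in NZO (20.9 ± 3.05 CPM, log2 fold change −0.94) and B6 (23.8 ± 3.7 CPM, −0.73). The glyoxalase gene Glo1, duplicated in some inbred strains, was highest in AJ at 212 ± 8.51 CPM, with 139 ± 28.7 CPM in Cast, 135 ± 10.5 CPM in 129 and 50.6 ± 6.49 CPM in NZO. Mx1, an antiviral gene that is defective in most classical strains, reached 44.9 ± 20.5 CPM in NZO. The complement component gene Hc was called in no strain, with its lowest adjusted p = 0.0651 in PWK (1.49 ± 0.668).

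Among the 28 strain pairs, the fewest genes differed between 129 and AJ (1823) and between B6 and NOD (1920). All 6 pairs within 129, AJ, B6 and NOD had at most 2490 called genes, and the other 22 pairs had at least 6259. Cast and NZO lay farthest apart, with 11260 genes.

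Fixed lists of genes for fat cell functions, immune cells and other tissues moved with strain in every contrast. Camera called 97 of 297 pairs of list and contrast, and permutation of the strain labels called 125, with 81 called by both. With an estimated correlation camera called 0 of 297. A directional test of the same lists with fry, which does not compare a list with other genes, called 130. Lists for fatty acid oxidation, thermogenesis, nuclear oxidative phosphorylation and mitochondrially encoded genes followed log2 Xist (r = 0.708 to 0.981). This held within 129, AJ, B6, Cast, PWK and WSB (n = 7 or 8) and was seen after the tests. Strain differences in them lie unevenly among libraries. Other called lists followed Xist in some or all strains, from r = -0.972 (cytokines, WSB) to 0.974 (ribosomal proteins, B6). With Xist as a covariate camera kept all 97 calls. This decides nothing, as random relabelling of libraries gave 92 to 138 calls.

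**Figure D2:**
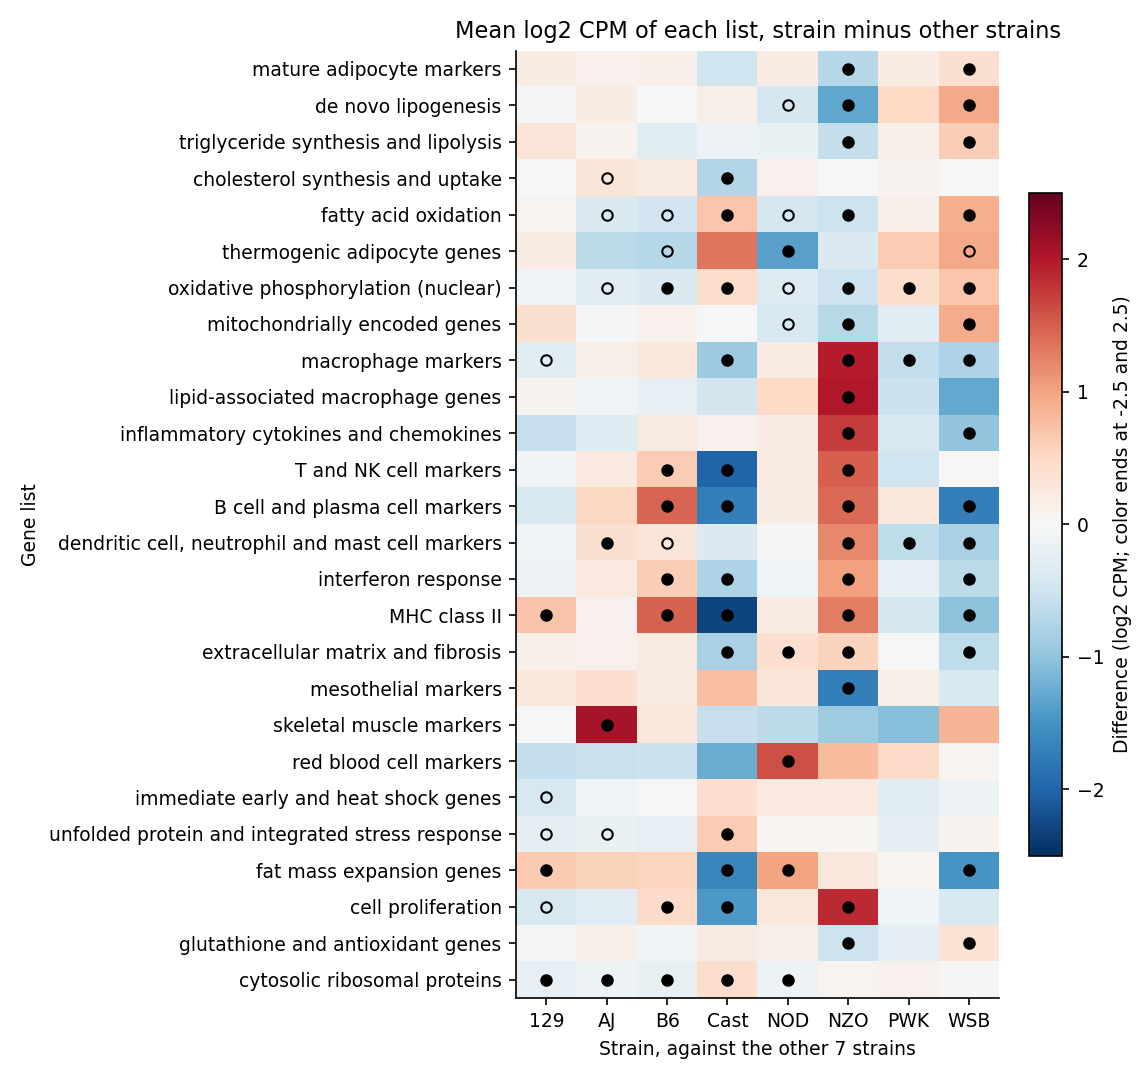
Color shows the mean log2 CPM of each gene list in 1 strain minus the other strains, for 26 lists (vertical axis) and 8 strains (horizontal axis), on a scale from −2.5 to 2.5. A filled dot marks lists called by camera and by permutation and an open dot lists called by camera alone, and macrophage markers are high in NZO (1.97) and low in Cast (−0.91) and WSB (−0.77), while T and NK cell markers are low in Cast (−2) but not in WSB (0.01).

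NZO, an obese strain, had high levels of immune cell transcripts and low levels of transcripts for fat synthesis. Of 23 macrophage markers 21 rose and 1 fell (1.97 ± 0.17, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 1.48e-25, estimated p = 0.394). All 16 genes of lipid-associated macrophages rose (2.01 ± 0.26, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 1.51e-07, estimated p = 0.614). Over the same libraries 16 of 20 genes of de novo lipogenesis fell and none rose (-1.29 ± 0.23, 8 of 8 libraries, permutation p = 0.000124, camera p = 0.000205, estimated p = 0.967). Of 10022 called genes, 5065 were higher and 4957 lower.

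Macrophage markers were among the clearest changes in NZO. The membrane protein gene Ms4a7 (4.31 ± 0.21, 51.1 ± 26.1 against 5.47 CPM, adjusted p = 1.16e-24, 8 of 8 libraries) and the Fc receptor gene Fcgr1 (3.31 ± 0.25) rose, as did the actin-bundling gene Aif1 (3.07 ± 0.22), while Cd163, the scavenger receptor of resident macrophages, fell (-1.72 ± 0.24, 44.4 ± 33.7 against 155 CPM). Adjusted over the list alone, 22 passed. Lipid-associated macrophage genes included the osteopontin gene Spp1 (4.2 ± 0.47), the vacuolar pump gene Atp6v0d2 (4.17 ± 0.42), Gpnmb (3.47 ± 0.39) and the elastase gene Mmp12 (3.78 ± 0.51), which with Xist as a covariate came to 5.07, 5.21, 4.4 and 5.38. Cytokine and chemokine genes rose in 17 of 21 and fell in 1 (1.75 ± 0.26, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 2.67e-05, estimated p = 0.967). Higher were Ccl3 (4.21 ± 0.41) and Il1rn (3.38 ± 0.38, or 4.0 with Xist). T and NK cell markers rose in 23 of 24 (1.49 ± 0.14, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 9.64e-13, estimated p = 0.426). The granzyme gene Gzma (3.75 ± 0.25) was among them. MHC class II genes, which present peptides to T cells, rose in 8 of 11 (1.28 ± 0.20, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 3.08e-06, estimated p = 0.764). H2-Eb1 (3.68 ± 0.18) and the class II transactivator gene Ciita (1.87 ± 0.18) were among them. Interferon response genes rose in 26 of 30 (1.03 ± 0.18, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 3.06e-06, estimated p = 0.967). The antiviral genes Mx1 (4.4 ± 0.32) and Oas3 (2.62 ± 0.37) were up and Mx2 (-5.97 ± 0.58) down.

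Cell division and matrix transcripts rose beside the immune lists. All 24 proliferation genes rose (1.86 ± 0.19, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 2.92e-20, estimated p = 0.426). The survivin gene Birc5 (2.5 ± 0.23) and Mki67 (2.33 ± 0.23) were among them. Of 29 genes of extracellular matrix and fibrosis 20 rose and none fell (0.56 ± 0.12, 7 of 8 libraries, permutation p = 6.6e-05, camera p = 0.00392, estimated p = 0.967). Collagen gene Col1a1 (1.05 ± 0.20) was among them. Mesothelial markers, from the lining of visceral organs, fell in 13 of 14 (-1.71 ± 0.24, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.000161, estimated p = 0.967). Upk3b (-2.01 ± 0.33) and Krt19 (-2.05 ± 0.36) were among them. Most of this fall lay in 4 libraries, with list means of 1.488 to 2.135 against 3.252 to 4.116 in the other 4 and strain means of 3.87 to 4.87 elsewhere, and the list went against log2 Xist within NZO (r = -0.908, n = 8).

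Neutrophil genes in NZO rested largely on replicate 8, and B cell markers in part. In that library the neutrophil granule gene Ngp stood at 560 CPM against 0.25 to 2.48 CPM in the other 7, and the B cell marker sum at 4750 against 330 to 1010 CPM. Over all 8 libraries, B cell markers rose in 17 of 19 (1.41 ± 0.27, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 2.82e-05, estimated p = 0.967), and dendritic cell, neutrophil and mast cell markers in 15 of 19 with 1 lower (1.2 ± 0.15, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.00153, estimated p = 0.442). Ngp (8.5 ± 0.66) came to 2.39 without replicate 8, the peroxidase gene Mpo (7.97 ± 0.66) to 2.03, the calprotectin gene S100a8 (5.25 ± 0.49) to 2.32, the immunoglobulin gene Ighm (2.8 ± 0.29) to 1.96, the plasma cell gene Mzb1 (3.46 ± 0.38) to 1.45 and the acute phase gene Saa3 (4.39 ± 0.46) to 1.51, all still called. S100a9 (6.53 ± 0.59), the partner of S100a8, lost its call without it (1.28). Without it the list differences were 1.06 ± 0.246 for B cell markers and 1.01 ± 0.142 for the list with neutrophil genes. Cd209a, a dendritic cell gene, fell (-1.06 ± 0.25).

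**Figure D3:**
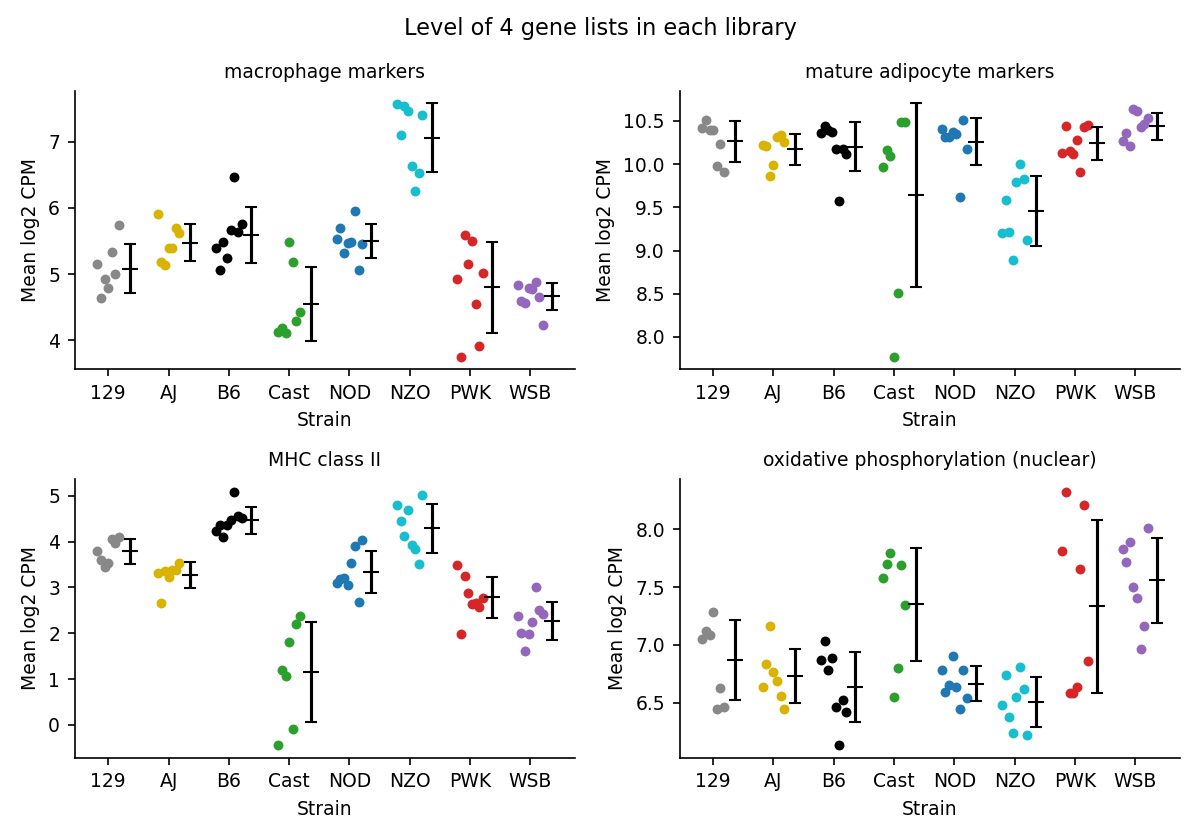
Each point is 1 library's mean log2 CPM over a gene list (vertical axis), by strain (horizontal axis), for macrophage, mature adipocyte, MHC class II and nuclear oxidative phosphorylation lists, with the mean ± SD per strain. NZO is highest in macrophage markers.

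Fat cell transcripts moved the other way in NZO. Mature adipocyte markers fell in 15 of 20 (-0.72 ± 0.16, 8 of 8 libraries, permutation p = 0.00235, camera p = 0.00153, estimated p = 0.967). Lower were the adipsin gene Cfd (-3.15 ± 0.40, 311 ± 103 against 3160 CPM, adjusted p = 1.46e-09, 8 of 8 libraries) and the resistin gene Retn (-1.54 ± 0.24), and the leptin gene Lep rose (1.54 ± 0.46, 1810 ± 726 against 1060 CPM). Lipogenic genes that fell included Thrsp (-3.43 ± 0.51), a regulator of lipid synthesis, and the fatty acid elongase gene Elovl6 (-2.48 ± 0.70). Genes of triglyceride synthesis and lipolysis fell in 13 of 20 (-0.59 ± 0.14, 8 of 8 libraries, permutation p = 0.00083, camera p = 0.00813, estimated p = 0.967). The acyltransferase gene Gpam (-1.3 ± 0.22) was among them. Of 51 nuclear genes of oxidative phosphorylation 47 fell and none rose (-0.52 ± 0.15, 8 of 8 libraries, permutation p = 0.00437, camera p = 3.59e-06, estimated p = 0.967). Sdha (-0.85 ± 0.20) and Ndufa5 (-0.89 ± 0.17) were among them. Mitochondrially encoded genes fell in 11 of 13 (-0.69 ± 0.24, 8 of 8 libraries, permutation p = 0.0154, camera p = 0.0252, estimated p = 0.967). One of them was mt-Atp8 (-1.19 ± 0.36), and with the 9 genes that share reads left out camera no longer called that list. Fatty acid oxidation genes fell in 15 of 23 (-0.51 ± 0.21, 7 of 8 libraries, permutation p = 0.0408, camera p = 0.0151, estimated p = 0.967). The peroxisomal gene Ehhadh (-1.48 ± 0.34) and the dehydrogenase gene Acadl (-1.04 ± 0.25) were down and Cpt1a, which moves fatty acids into mitochondria, up (0.63 ± 0.13). Antioxidant genes fell in 12 of 23 (-0.53 ± 0.052, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.00193, estimated p = 0.426). The glutathione transferase gene Gsta3 (-2.49 ± 0.25) and the superoxide dismutase gene Sod1 (-1.02 ± 0.15) were down and the heme oxygenase gene Hmox1 up (1.13 ± 0.26).

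Single genes stood far apart in NZO. The cytochrome P450 gene Cyp2e1 (-7.05 ± 0.52, 13.4 ± 9.36 against 3090 CPM, adjusted p = 1.93e-17, 8 of 8 libraries) fell, and the tryptophan hydroxylase gene Tph2 (7.41 ± 0.45, 63.4 ± 52.4 against 3.16 CPM, adjusted p = 2.16e-20, 8 of 8 libraries) rose, though Tph2 stood at 0.973 CPM in replicate 8 against 14.6 to 152 CPM in the other 7. Also lower were the lipid transporter gene Mfsd2a (-4.59 ± 1.13), with -3.34 without 6 libraries rich in genital duct markers, and the major urinary protein gene Mup17 (-4.8 ± 1.96, shares reads), whose call ended without replicate 8 (-4.6) and which came to -3.45 without 7 rich in liver markers.

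WSB, a wild-derived strain, showed high levels of transcripts for fat synthesis, fat oxidation and respiration. Of 23 genes of fatty acid oxidation 22 rose and 1 fell (0.90 ± 0.21, 8 of 8 libraries, permutation p = 0.000623, camera p = 6.03e-06, estimated p = 0.967). De novo lipogenesis genes rose in 15 of 20 (0.95 ± 0.23, 8 of 8 libraries, permutation p = 0.000696, camera p = 0.000166), and nuclear oxidative phosphorylation genes in 50 of 51 (0.69 ± 0.15, 8 of 8 libraries, permutation p = 0.000554, camera p = 9.92e-12), each with estimated p = 0.967. Genes of extracellular matrix and fibrosis fell in 23 of 29 and none rose (-0.64 ± 0.12, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 5.5e-05, estimated p = 0.967). Within WSB (n = 8), as was seen after the tests, the first 3 lists followed log2 Xist (r = 0.926, 0.877 and 0.789). Their list means were 8.543 to 8.82, 9.156 to 9.748 and 7.716 to 8.013 in 4 libraries against 7.357 to 7.702, 8.079 to 8.64 and 6.961 to 7.498 in the other 4, so much of each difference lay in part of the libraries. With Xist as a covariate the differences were 0.95 ± 0.161, 0.986 ± 0.209 and 0.723 ± 0.118. In all, 9180 genes were called, 4769 higher and 4411 lower.

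Adipocyte genes in WSB were split. Of the mature adipocyte markers 13 of 20 rose (0.41 ± 0.16, 8 of 8 libraries, permutation p = 0.0482, camera p = 0.00407, estimated p = 0.967). Cfd (1.83 ± 0.27, adjusted p = 8.48e-08, 7 of 8 libraries) and Retn (1.19 ± 0.19) were up and leptin down (-3.16 ± 0.67, 105 ± 180 against 1300 CPM). Leptin stood at 539 CPM in WSB replicate 7 against 5.37 to 124 CPM in the other 7, and without that library its change was -4.45. Replicate 7 held 1500 CPM of Cfd against 4410 to 10300 CPM in the other 7 libraries. Lipogenic examples were Elovl6 (2.36 ± 0.48), Thrsp (1.73 ± 0.34) and Acacb (2.28 ± 0.25). Oxidation examples were Ehhadh (1.84 ± 0.26), Acadl (1.33 ± 0.21) and Pdk4 (1.75 ± 0.27), and Cpt1a fell (-0.75 ± 0.15). Triglyceride synthesis and lipolysis genes rose in 11 of 20 (0.61 ± 0.14, 8 of 8 libraries, permutation p = 0.000594, camera p = 0.00362, estimated p = 0.967). Cidea (2.01 ± 0.53) was among them. A respiratory chain example was Cox7b (0.92 ± 0.17). Mitochondrially encoded genes rose in 12 of 13 (0.92 ± 0.24, 8 of 8 libraries, permutation p = 0.00151, camera p = 0.000893, estimated p = 0.967), a camera call that ended without the 9 that share reads. List means were 12.32 to 12.59 in replicates 1, 3, 4 and 9 and 10.93 to 11.21 in the rest (r = 0.949 with log2 Xist). Genes of fat mass expansion, whose levels follow growth of fat depots, fell in 9 of 14 (-1.48 ± 0.21, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.015, estimated p = 0.967). The bone morphogenetic protein gene Bmp3 (-2.71 ± 0.28) was down and the vascular growth factor gene Vegfa up (0.43 ± 0.11). Antioxidant genes rose in 14 of 23 (0.37 ± 0.052, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.00593, estimated p = 0.442). Gpx3 (1.49 ± 0.19) and Sod1 (1.02 ± 0.13) were up and Sod3 (-1.12 ± 0.18) down.

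Thermogenic genes were high in WSB by camera but not by permutation, and not without Cast replicates 5 and 6 (camera p = 0.0513). Of 17 genes 13 rose (0.95 ± 0.46, 5 of 8 libraries, permutation p = 0.0919, camera p = 0.0309, estimated p = 0.967). List means followed log2 Xist (r = 0.981, n = 8), with 5.32 to 5.85 in 4 libraries and 2.452 to 2.869 in the other 4. The elongase gene Elovl3 (3.3 ± 0.53) of brown fat rose. Uncoupling protein gene Ucp1 (2.5 ± 0.80) rose too, but its call ended with replicate number as a block (1.31), with 2 surrogate variables, without 4 libraries rich in muscle transcripts, and on the deposited variance-stabilised values.

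Most immune lists were low in WSB, but T and NK cell markers were not called, with 6 higher and 3 lower of 24 (0.01 ± 0.14, 3 of 8 libraries, permutation p = 0.972, camera p = 0.798, estimated p = 0.999). Macrophage markers fell in 19 of 23 (-0.77 ± 0.17, 8 of 8 libraries, permutation p = 0.000469, camera p = 0.000205, estimated p = 0.967). The protease gene Ctss (-1.69 ± 0.31) and Cd68 (-1.31 ± 0.29) were among them. B cell markers fell in 18 of 19 (-1.71 ± 0.27, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 2.7e-05, estimated p = 0.967). Ighm (-2.52 ± 0.44) and the B cell receptor gene Cd79a (-2.31 ± 0.40) were among them. Mast cell protease genes led the fall of 9 of 19 dendritic cell, neutrophil and mast cell markers (-0.82 ± 0.15, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 0.00353, estimated p = 0.592). Cpa3 (-2.87 ± 0.30) and Cma1 (-2.25 ± 0.29) were among them. Cytokine and chemokine genes fell in 13 of 21 (-0.99 ± 0.26, 8 of 8 libraries, permutation p = 0.00286, camera p = 0.015, estimated p = 0.967). Ccl8 (-3.35 ± 0.50) and Saa3 (-3.38 ± 0.83) were among them. Interferon response genes fell in 23 of 30 (-0.66 ± 0.18, 8 of 8 libraries, permutation p = 0.00282, camera p = 0.000789, estimated p = 0.967). Mx1 (-3.05 ± 0.56) and Rsad2 (-1.86 ± 0.30) were down and Ifi27l2a (2.23 ± 0.33) up. MHC class II genes fell in 7 of 11 (-1.03 ± 0.20, 8 of 8 libraries, permutation p = 0.000178, camera p = 0.00845, estimated p = 0.967). H2-Eb1 (-5.56 ± 0.35) and H2-Ob (-1.1 ± 0.31) were among them. Matrix genes that fell included Col6a2 (-1.11 ± 0.19) and the tenascin gene Tnc (-1.27 ± 0.16).

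Among single genes in WSB, the sialyltransferase gene St6galnac5 (5.02 ± 0.25, adjusted p = 4.32e-24, 8 of 8 libraries) and the retinoic acid responsive gene Rarres1 (4.8 ± 0.23) rose, as did Cwc22 (5.68 ± 0.0661, shares reads). The cartilage gene Crtac1 (-6.01 ± 0.73), which came to -7.19 without replicate 7, and Wfdc21 (-6.72 ± 0.78) fell, the latter with -8.13 without liver-rich libraries. Zfp738 had 1 count in all 8 WSB libraries together, in replicate 7, 0.0401% of its level in the other strains with a 95% counting interval of 0.00139 to 0.307%. Intervals of this kind cover counting error only.

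Cast, another wild-derived strain, combined high levels of transcripts for fat oxidation with low levels of matrix and fat mass transcripts and of most immune lists. All 24 T and NK cell markers fell (-2.0 ± 0.15, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 6.34e-10, estimated p = 0.426), and MHC class II genes fell in 9 of 11 (-2.3 ± 0.21, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 1.51e-07, estimated p = 0.572). Of 23 fatty acid oxidation genes 15 rose and 1 fell (0.70 ± 0.22, 6 of 7 libraries, permutation p = 0.00758, camera p = 0.0125, estimated p = 0.967). Its list means were 8.319 to 8.563 in 3 libraries and 6.739 to 7.966 in the other 4 (r = 0.793 with log2 Xist, n = 7). Genes of fat mass expansion fell in 10 of 14 (-1.64 ± 0.22, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 0.0151, estimated p = 0.967). Of 10451 called genes, 5498 were higher and 4953 lower.

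T cell genes in Cast included the receptor subunit gene Cd3g (-3.61 ± 0.39) and the coreceptor gene Cd8a (-3.64 ± 0.48). Class II examples were H2-Aa (-2.91 ± 0.26), the invariant chain gene Cd74 (-2.69 ± 0.25) and Ciita (-2.91 ± 0.28). B cell markers fell in 17 of 19 (-1.72 ± 0.28, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 0.000893, estimated p = 0.967). Ighm (-3.78 ± 0.52) and the kinase gene Blk (-2.75 ± 0.47) were among them. Macrophage markers fell in 10 and rose in 3 of 23 (-0.91 ± 0.18, 6 of 7 libraries, permutation p = 0.000124, camera p = 0.0221, estimated p = 0.967). Ms4a7 (-6.76 ± 0.52), the chemokine receptor gene Ccr2 (-2.23 ± 0.29) and Ctss (-1.79 ± 0.33) were down and the lipopolysaccharide receptor gene Cd14 (2.12 ± 0.26) up. Interferon response genes fell in 13 and rose in 7 of 30 (-0.77 ± 0.19, 6 of 7 libraries, permutation p = 0.000696, camera p = 0.0205, estimated p = 0.984). Ifi44 (-2.59 ± 0.41) and Ifit2 (-1.37 ± 0.20) were down and Mx2 (4.69 ± 0.27) up. Proliferation genes fell in 21 of 24 (-1.44 ± 0.21, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 1.89e-05, estimated p = 0.967). The mitotic kinase gene Bub1 (-2.56 ± 0.50) and Birc5 (-2.31 ± 0.36) were among them. Matrix genes fell in 20 of 29 (-0.80 ± 0.12, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 0.000325, estimated p = 0.967). Tnc (-2.01 ± 0.18) and collagen gene Col6a1 (-1.52 ± 0.19) were down and the protease inhibitor gene Timp1 up (1.97 ± 0.41), a call that ended on the variance-stabilised values.

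Metabolic changes in Cast were led by Ehhadh (3.7 ± 0.24, 989 ± 1030 against 99 CPM, adjusted p = 2.7e-19, 7 of 7 libraries) and Pdk4 (1.57 ± 0.28), against a fall of Cpt1a (-0.39 ± 0.15). Nuclear oxidative phosphorylation genes rose in 38 of 51 (0.45 ± 0.16, 6 of 7 libraries, permutation p = 0.0177, camera p = 0.00112, estimated p = 0.984). Uqcrc1 (0.87 ± 0.18) was among them. Cholesterol synthesis and uptake genes fell in 14 of 23 (-0.73 ± 0.14, 6 of 7 libraries, permutation p = 0.00028, camera p = 0.00407, estimated p = 0.967). Sc5d (-1.2 ± 0.22) was among them. In the fat mass list, neuronatin gene Nnat (-4.43 ± 0.73) fell, with -5.05 without Cast replicate 8, as did leptin (-4.02 ± 0.76, 62.2 ± 57.5 against 1310 CPM), and Vegfa rose (0.95 ± 0.12). Ribosomal protein genes rose in 45 of 52, a list in which 41 share reads (0.44 ± 0.0552, 7 of 7 libraries, permutation p = 6.6e-05, camera p = 8.06e-13, estimated p = 0.967), and without those camera did not call the list.

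Cast replicates 5 and 6 stood apart from the other 5 Cast libraries, as was seen after the tests. Genes of the unfolded protein and integrated stress response rose in 15 of 20 (0.63 ± 0.12, 6 of 7 libraries, permutation p = 0.000512, camera p = 0.000334, estimated p = 0.967), but this rested on those libraries, with list means of 8.01 and 7.51 against 5.96 to 6.53. Without them the difference was 0.174 ± 0.0696 and camera did not call the list (adjusted p = 0.482). The glutathione-degrading gene Chac1 (2.92 ± 0.21) came to 1.45 and the pseudokinase gene Trib3 (1.91 ± 0.20) to 0.72, both still called. Mature adipocyte markers were low in the 2 libraries (7.77 and 8.51 against 9.97 to 10.5) and cytokine genes high (3.97 and 3.07 against 0.753 to 1.15), as were immediate early genes (6.65 and 5.67 against 4.49 to 5.15). Without them Cd14 (0.22) and Cpt1a (-0.32) lost their calls, Timp1 turned to -1.44 (adjusted p = 0.0114), and Mx2 came to 2.32. The other lists that camera called in Cast kept their call, but without the 2 libraries the differences were -1.34 ± 0.142 for interferon response and 0.725 ± 0.175 for nuclear oxidative phosphorylation, and those of genes came to -2.12 for Ifit2, -3.51 for Ifi44, -2.96 for Ccr2 and 3.07 for Ehhadh. Cytokine genes, not called in Cast (0.106 ± 0.278, permutation p = 0.779), came to -0.635 ± 0.256.

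Large single changes in Cast were the calcium-binding protein gene Calb1 (10.15 ± 0.30, adjusted p = 9.24e-36, 7 of 7 libraries), and the drug-metabolizing cytochrome gene Cyp2b10 (7.09 ± 0.28). The serpin gene Serpina3k (7.05 ± 0.51, shares reads) rose (8.05 without liver-rich libraries). Fam213b (-7.72 ± 0.36) fell, with -8.35 without Cast replicate 8. Tph2 had 1 count in the 7 Cast libraries, in replicate 8, a ratio of 0.0337% to the other strains (95% counting interval 0.000809 to 0.178%), and its log2 fold change of -7.6 ± 1.69 became -8.76 without that library. 9930111J21Rik1 had 3 counts, all in replicate 5, a ratio of 0.124% (0.0351 to 0.497%), and its change of -8.46 ± 0.39 became -10.66 without replicates 5 and 6.

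A mitochondrial transcript, chosen after its values were seen, was near 0 in Cast and PWK. The cytochrome oxidase gene mt-Co2 had 16.8 ± 14.9 CPM in Cast (SD, n = 7) and 38.2 ± 29.9 CPM in PWK (SD, n = 8), against strain means of 1500 to 4290 CPM elsewhere. Its 2 copies in the nuclear genome had 7730 ± 3680 CPM in Cast and 10400 ± 7490 CPM in PWK. The sum of gene and copies relative to mt-Cytb was 0.515 ± 0.0633 in Cast and 0.652 ± 0.044 in PWK, where the lowest other strain mean was 0.574 ± 0.0437, in B6.

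**Figure D4:**
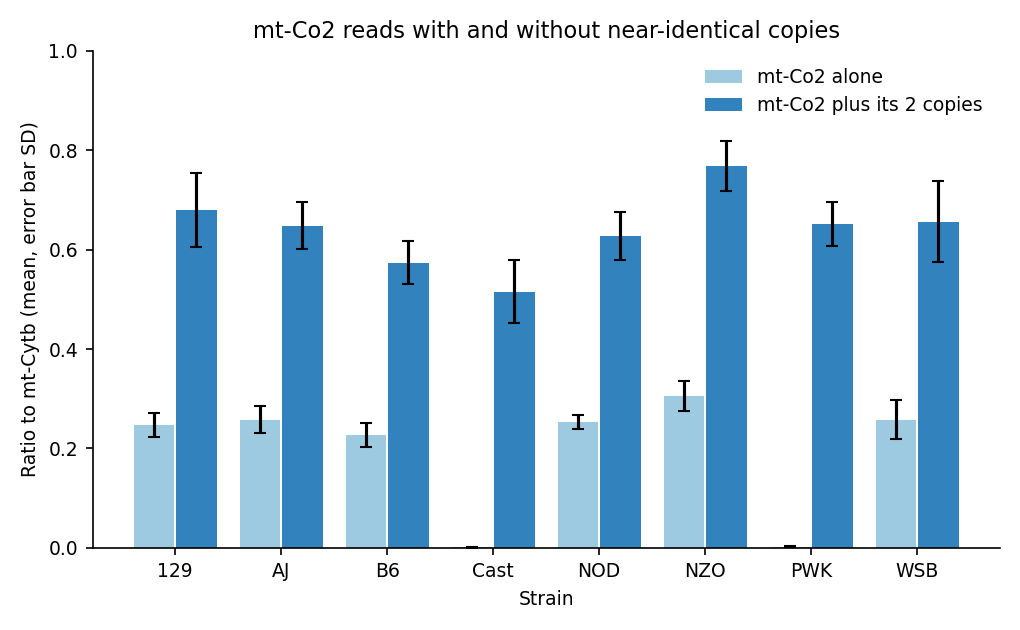
Bars give CPM of mt-Co2 alone and of mt-Co2 with its 2 nuclear copies, each divided by CPM of mt-Cytb (vertical axis), by strain (horizontal axis), with SD over libraries as error bars. Alone, the ratio was 0.0011 in Cast and 0.00251 in PWK against 0.227 to 0.305 elsewhere.

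PWK, the remaining wild-derived strain, had high respiratory chain transcripts and low macrophage, dendritic cell, neutrophil and mast cell markers. Of 51 nuclear oxidative phosphorylation genes 44 rose and none fell (0.43 ± 0.15, 5 of 8 libraries, permutation p = 0.0164, camera p = 2.67e-05, estimated p = 0.967). Ndufv1 (0.89 ± 0.16), Cyc1 (0.88 ± 0.19) and Sdhb (0.86 ± 0.18) were among them. Macrophage markers fell in 10 of 23 (-0.62 ± 0.17, 6 of 8 libraries, permutation p = 0.00341, camera p = 0.00787, estimated p = 0.967). Ms4a7 (-2.42 ± 0.34), Fcgr1 (-1.29 ± 0.36) and Cd14 (-0.93 ± 0.32) were among them. Dendritic cell, neutrophil and mast cell markers fell in 9 and rose in 3 of 19 (-0.64 ± 0.15, 7 of 8 libraries, permutation p = 0.00072, camera p = 0.0422, estimated p = 0.967). Cd209a (-3.12 ± 0.30) and the mast cell genes Mcpt4 (-2.04 ± 0.32), Tpsb2 (-1.42 ± 0.24) and Cma1 (-1.34 ± 0.27) were down. The respiratory list followed log2 Xist within PWK (r = 0.926, n = 8), with means of 7.659 to 8.326 in 4 libraries and 6.579 to 6.859 in the other 4, and macrophage markers went against it (r = -0.78), so both differences lay mostly in part of the libraries. With Xist as a covariate they were 0.42 ± 0.118 and -0.607 ± 0.156. This was looked at after the tests. In all, 8105 genes were called, 4573 higher and 3532 lower.

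Liver marker transcripts summed to 469 ± 551 CPM in PWK libraries (SD, n = 8) and 199 ± 380 CPM over all 61. Without the 7 libraries above 500 CPM of them, Cyc1 (0.44), Sdhb (0.48) and Cd14 (-0.70) lost their calls. Mup17, a liver product that shares reads, went from 6.3 ± 0.72 to 2.31. Mpo in PWK (2.79 ± 0.76) rested on replicate 1, with 9.71 CPM against at most 0.111 CPM in the other 7. It was 3.63 without NZO replicate 8, and its call ended with the replicate block (2.36).

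Among single genes in PWK, Mmd2 (4.86 ± 0.51, 44.7 ± 56.2 against 5.37 CPM, adjusted p = 8.22e-12, 8 of 8 libraries) rose, with 3.68 without the liver-rich libraries, and the interferon-induced gene Ifi27l2a (-7.5 ± 0.65, adjusted p = 1.78e-14, 8 of 8 libraries), Zfp605 (-6.84 ± 0.26) and St6galnac5 (-5.83 ± 0.55) fell.

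B6, the reference strain of the mouse genome, had high levels of lymphocyte and antigen presentation transcripts. MHC class II genes rose in 10 of 11 (1.48 ± 0.20, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 8.25e-14, estimated p = 0.394). H2-Eb1 (2.75 ± 0.18, adjusted p = 2.06e-18, 8 of 8 libraries), H2-Ab1 (1.63 ± 0.18) and H2-Ob (1.39 ± 0.25) were among them. B cell markers rose in 17 of 19 (1.46 ± 0.27, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 1.39e-08, estimated p = 0.764). Ms4a1 (1.58 ± 0.32) and Ighm (1.7 ± 0.31) were among them. T and NK cell markers rose in 11 of 24 (0.63 ± 0.14, 8 of 8 libraries, permutation p = 0.000623, camera p = 0.000166, estimated p = 0.967). Cd2 (1.56 ± 0.18) and Cd8b1 (1.94 ± 0.32) were among them. Interferon response genes rose in 15 of 30 (0.62 ± 0.18, 8 of 8 libraries, permutation p = 0.00418, camera p = 0.000261, estimated p = 0.967). Rsad2 (1.4 ± 0.22), Ifi44 (1.07 ± 0.28) and Oas2 (0.98 ± 0.27) were among them. Of 4899 called genes, 2722 were higher and 2177 lower.

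Respiratory genes were low in B6 and proliferation genes high. Nuclear oxidative phosphorylation genes fell in 24 of 51 (-0.36 ± 0.15, 5 of 8 libraries, permutation p = 0.0455, camera p = 8.44e-07, estimated p = 0.967). Most of this lay in 4 libraries, with list means of 6.131 to 6.518 against 6.782 to 7.03 in the other 4 (r = 0.935 with log2 Xist, n = 8). Sdhb (-0.65 ± 0.20) and Uqcrc1 (-0.58 ± 0.20) were among the genes that fell. Proliferation genes rose in 9 of 24 (0.49 ± 0.19, 7 of 8 libraries, permutation p = 0.0368, camera p = 0.0124, estimated p = 0.967). Bub1b (1.55 ± 0.20) and Mki67 (0.87 ± 0.25) were among them. Ribosomal protein genes fell in 20 of 52, a list in which 41 share reads (-0.18 ± 0.0522, 8 of 8 libraries, permutation p = 0.00508, camera p = 8.44e-07, estimated p = 0.967). Camera, but not permutation, called 3 further lists in B6. Fatty acid oxidation had 10 of 23 genes lower (-0.49 ± 0.21, 5 of 8 libraries, permutation p = 0.0515, camera p = 0.0036, estimated p = 0.967), again with list means of 6.344 to 6.744 in 4 libraries and 7.049 to 7.356 in the other 4. Pdk4 (-1.57 ± 0.35) and Acaa2 (-0.94 ± 0.28) were among them. Thermogenic genes had 5 of 17 lower (-0.72 ± 0.46, 6 of 8 libraries, permutation p = 0.206, camera p = 0.0418, estimated p = 0.967), a call that ended without genes that share reads (camera p = 0.127). The coactivator gene Ppargc1a (-1.17 ± 0.32) and Cidea (-2.04 ± 0.73) were among them. Dendritic cell, neutrophil and mast cell markers had 9 of 19 higher (0.30 ± 0.15, 8 of 8 libraries, permutation p = 0.112, camera p = 0.0205, estimated p = 0.967), one of them Cd209a (2.68 ± 0.18). In the last of these the median log2 fold change of 0.42 and the test pointed up and the mean of −0.04 down.

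Genital duct markers summed to 241 ± 450 CPM in B6 (SD, n = 8). Without the 6 duct-rich libraries, all low in Xist, the calls of Sdhb (-0.56), Uqcrc1 (-0.53) and Cidea (-1.78) ended. Without the liver-rich libraries Mki67 (0.68), Uqcrc1 (-0.47) and Cidea (-1.74) lost theirs. Ngp (-4.39 ± 1.59) and Mpo (-4.94 ± 1.65) were lower in B6 and still called without NZO replicate 8 (-3.56 and -4.11). Both calls ended without the duct-rich libraries (-4.02 and -4.59) and on the variance-stabilised values (-0.56 and -0.47), and that of Ngp without the liver-rich (-4.3). Among single genes in B6, the netrin receptor gene Unc5a (4.35 ± 0.23), the corneodesmosin gene Cdsn (3.87 ± 0.24) and the vanin gene Vnn3 (3.42 ± 0.25) rose, and the interferon-inducible gene Ifi202b (-6.45 ± 0.50, adjusted p = 7.78e-16, 8 of 8 libraries) fell.

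NOD, a strain prone to autoimmune diabetes, had low levels of thermogenic transcripts and high levels of matrix and fat mass transcripts. Of 17 thermogenic genes 10 fell and none rose (-1.36 ± 0.46, 8 of 8 libraries, permutation p = 0.0135, camera p = 0.0033, estimated p = 0.967). Ucp1 (-6.13 ± 1.52, 2.73 ± 3.17 against 272 CPM, adjusted p = 0.0017, 8 of 8 libraries), Elovl3 (-2.72 ± 0.85) and Cidea (-2.33 ± 0.75) were among them. Genes of fat mass expansion rose in 9 of 14 (0.99 ± 0.21, 8 of 8 libraries, permutation p = 0.000469, camera p = 0.00144, estimated p = 0.917). The Wnt inhibitor gene Sfrp5 (2.22 ± 0.56), the natriuretic peptide receptor gene Npr3 (1.27 ± 0.31) and Lep (1.39 ± 0.46) were up and Vegfa down (-0.49 ± 0.12). Matrix genes rose in 8 of 29 (0.43 ± 0.12, 7 of 8 libraries, permutation p = 0.00205, camera p = 0.00245, estimated p = 0.967). The thrombospondin gene Thbs1 (2.08 ± 0.26) and Sparc (0.59 ± 0.15) were among them. Of 4931 called genes, 2732 were higher and 2199 lower.

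**Figure D5:**
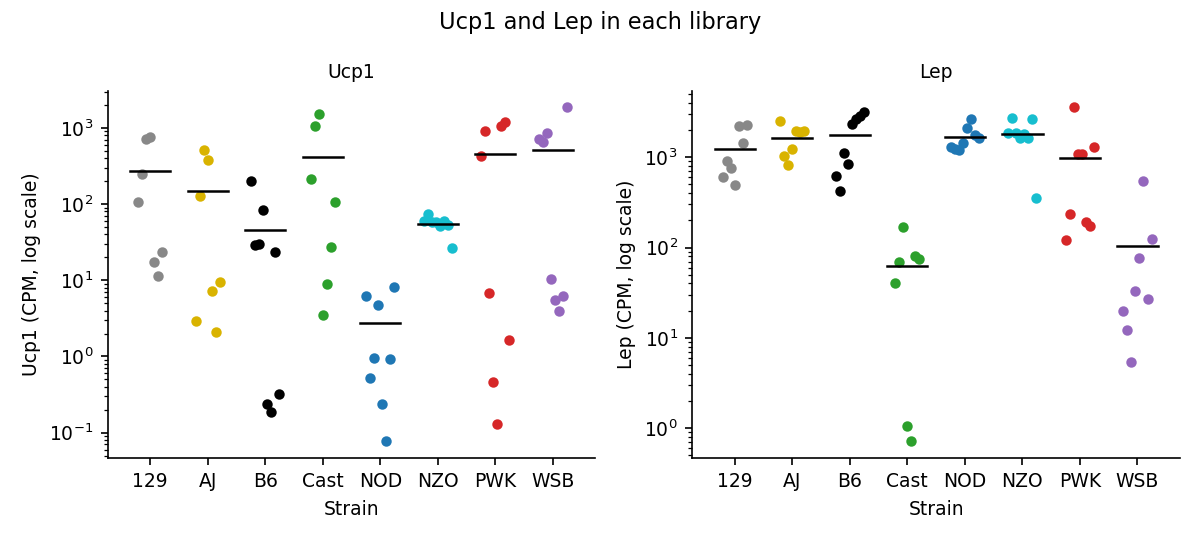
Each point is 1 library's CPM of Ucp1 or of Lep on a log axis (vertical), by strain (horizontal axis), and the line is the arithmetic mean of the strain. Ucp1 ran from 0.0774 to 8.13 CPM in NOD and Lep from 0.72 to 169 CPM in Cast.

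Ucp1 in NOD came to -3.88 with 2 surrogate variables and -4.32 with Xist as a covariate, Cidea with Xist to -1.6 and Sfrp5 to 3.31, and Elovl3 lost its call with Xist (-1.82), with the replicate block (-2.02) and with 2 surrogate variables (-1.58). Red blood cell markers rose in 5 of 7, a list in which 5 share reads (1.61 ± 0.22, 8 of 8 libraries, permutation p = 6.6e-05, camera p = 8.44e-07, estimated p = 0.426), and ribosomal protein genes fell in 13 of 52 (-0.13 ± 0.0522, 7 of 8 libraries, permutation p = 0.0376, camera p = 0.000325, estimated p = 0.967), a call that ended without the 41 that share reads. Camera, but not permutation, called 4 lists as lower in NOD. De novo lipogenesis had 7 of 20 genes lower (-0.43 ± 0.23, 6 of 8 libraries, permutation p = 0.136, camera p = 0.0382), and fatty acid oxidation 7 of 23 (-0.44 ± 0.21, 7 of 8 libraries, permutation p = 0.0816, camera p = 0.00885), each with estimated p = 0.967. Nuclear oxidative phosphorylation had 24 of 51 lower (-0.33 ± 0.15, 7 of 8 libraries, permutation p = 0.0706, camera p = 5.18e-06), and mitochondrially encoded genes 10 of 13 (-0.40 ± 0.24, 7 of 8 libraries, permutation p = 0.175, camera p = 0.0338), each with estimated p = 0.967. Without genes that share reads camera no longer called fatty acid oxidation (0.0582) or the mitochondrially encoded genes (0.0721). Among their members, the transcription factor genes Mlxipl (-1.25 ± 0.29) and Ppara (-1.52 ± 0.41) fell, as did Acadl (-1.03 ± 0.25), Uqcrfs1 (-0.71 ± 0.20), Cyc1 (-0.60 ± 0.21) and mt-Cytb (-0.82 ± 0.25). On the variance-stabilised values Cidea and Cyc1 lost their calls. Single genes that rose in NOD were Tcerg1l (8.71 ± 0.31, 39.5 ± 15.1 against 0.148 CPM, adjusted p = 1.88e-30, 8 of 8 libraries), the potassium channel gene Kcnj15 (4.0 ± 0.34) and Rarres1 (3.67 ± 0.23). The eosinophil ribonuclease gene Ear2 (-3.4 ± 0.50) and Cdsn (-3.14 ± 0.41) fell.

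In AJ, dendritic cell, neutrophil and mast cell markers were high, as were skeletal muscle transcripts in replicates 3 and 4. The former rose in 10 and fell in 1 of 19 (0.41 ± 0.16, 7 of 7 libraries, permutation p = 0.0392, camera p = 0.000157, estimated p = 0.426). The lectin gene Cd209a (2.49 ± 0.19) and the mast cell protease genes Mcpt4 (1.74 ± 0.25), Cma1 (1.46 ± 0.22) and Cpa3 (1.45 ± 0.22) were up. All 18 skeletal muscle markers rose (2.07 ± 0.62, 7 of 7 libraries, permutation p = 0.0151, camera p = 1.39e-08, estimated p = 0.967). The myosin gene Myh4 (8.63 ± 0.80), the parvalbumin gene Pvalb (6.11 ± 0.65) and the calcium release channel gene Ryr1 (4.81 ± 0.43) were among them. Muscle markers summed to 4010 CPM in AJ replicate 4 and 1980 CPM in replicate 3, while WSB replicates 1 and 9 held 738 and 426 CPM. Without these 4 libraries 2 of 18 markers were called higher in AJ, and the list's median log2 fold change went from 4.84 to 0.30. Myh4 (2.34), Pvalb (1.01) and the calcium pump gene Atp2a1 (6.83 ± 0.70, shares reads, then 0.96) lost their calls, and Ryr1 came to 1.02. Of 4277 called genes, 2493 were higher and 1784 lower.

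Camera, but not permutation, called 4 further lists in AJ. Cholesterol synthesis and uptake had 10 of 23 genes higher (0.31 ± 0.14, 5 of 7 libraries, permutation p = 0.0775, camera p = 0.0205, estimated p = 0.967). Lanosterol synthase gene Lss (0.89 ± 0.19) and Stard4 (0.80 ± 0.11) were among them. Fatty acid oxidation had 4 of 23 lower (-0.37 ± 0.22, 4 of 7 libraries, permutation p = 0.178, camera p = 0.015, estimated p = 0.967). Ehhadh (-1.26 ± 0.36) and Acadl (-0.95 ± 0.27) were among them. Nuclear oxidative phosphorylation had 2 of 51 lower, and 0 passed adjusted over the list alone (-0.26 ± 0.16, 5 of 7 libraries, permutation p = 0.185, camera p = 0.000205, estimated p = 0.977). Unfolded protein and integrated stress response genes had 4 of 20 lower (-0.17 ± 0.12, 6 of 7 libraries, permutation p = 0.247, camera p = 0.0486, estimated p = 0.967). The chaperone genes Dnajb9 (-0.65 ± 0.18) and Calr (-0.49 ± 0.11) were among them, and the call ended without Cast replicates 5 and 6 (0.0544) and without genes that share reads (0.0582). Ribosomal protein genes were lower in 11 of 52 (-0.14 ± 0.0552, 5 of 7 libraries, permutation p = 0.0429, camera p = 0.000366, estimated p = 0.967), a call that ended without the 41 that share reads. Among single genes in AJ, Disp2 (4.07 ± 0.21, adjusted p = 5.56e-23, 7 of 7 libraries), Unc5a (3.28 ± 0.25) and Pianp (2.76 ± 0.18) rose, and the basement membrane collagen gene Col4a6 (-4.83 ± 0.46) and the ADP-ribosyl cyclase gene Bst1 (-4.79 ± 0.49) fell. The neutrophil gene Retnlg fell (-2.65 ± 0.88), with -2.0 without NZO replicate 8, but its call ended without the muscle-rich libraries and on the variance-stabilised values (-0.53).

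129 had the fewest called genes, 3451, of which 2003 were higher and 1448 lower. MHC class II genes rose in 7 of 11 (0.71 ± 0.21, 7 of 7 libraries, permutation p = 0.00683, camera p = 0.00015, estimated p = 0.967). H2-Eb1 (2.07 ± 0.20), H2-Ab1 (1.0 ± 0.20) and Ciita (0.76 ± 0.20) were among them. Genes of fat mass expansion rose in 6 and fell in 1 of 14 (0.65 ± 0.22, 7 of 7 libraries, permutation p = 0.0154, camera p = 0.0309, estimated p = 0.967). Nnat (1.63 ± 0.44) and Bmp3 (0.89 ± 0.22) were up and Vegfa down (-0.37 ± 0.13). Ribosomal protein genes fell in 25 of 52, a list in which 41 share reads (-0.21 ± 0.0552, 7 of 7 libraries, permutation p = 0.00382, camera p = 1.66e-09, estimated p = 0.967). Camera, but not permutation, called 4 lists as lower. Macrophage markers had 5 of 23 lower (-0.29 ± 0.18, 6 of 7 libraries, permutation p = 0.181, camera p = 0.00807, estimated p = 0.967). Unfolded protein and integrated stress response genes had 5 of 20 lower (-0.24 ± 0.12, 7 of 7 libraries, permutation p = 0.108, camera p = 0.0151, estimated p = 0.967). Proliferation genes had 2 of 24 lower (-0.41 ± 0.21, 6 of 7 libraries, permutation p = 0.104, camera p = 0.00307), and immediate early and heat shock genes had 0 of 20 (-0.40 ± 0.20, 6 of 7 libraries, permutation p = 0.107, camera p = 0.024), each with estimated p = 0.967.

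Members of those lists that fell in 129 were the complement gene C1qa (-0.56 ± 0.14) and Aif1 (-1.0 ± 0.32), the replication genes Mcm6 (-1.66 ± 0.18) and Tk1 (-0.82 ± 0.18), and the stress response genes Xbp1 (-0.49 ± 0.13) and Ddit3 (-0.56 ± 0.20), while the asparagine synthetase gene Asns (0.51 ± 0.14) rose. Without the 6 libraries over 300 CPM of genital duct markers, 3 of them in 129, the calls of Aif1 (-1.1), Ciita (0.71), Xbp1 (-0.47), Nnat (1.32) and Vegfa (-0.35) ended. That of Aif1 also ended with the replicate block (-0.87), that of Vegfa without the muscle-rich libraries, and that of Ddit3 on the variance-stabilised values. Single genes that rose in 129 were the histidine ammonia-lyase gene Hal (3.81 ± 0.19, adjusted p = 2.06e-23, 7 of 7 libraries) and Kcnj15 (3.67 ± 0.36), the latter with 2.81 without the duct-rich libraries. Gdpd3 (5.66 ± 0.0988, shares reads) was among them. All 6 of the genes that fell most share reads, led by Trim5 (-6.75 ± 0.45, shares reads), with -7.81 without the duct-rich.

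Against the 5 classical strains, the 3 wild-derived strains were high in transcripts for fat oxidation, thermogenesis and respiration and low in those for antigen presentation, matrix and fat mass. Fatty acid oxidation genes rose in 22 and fell in 1 of 23 (0.81 ± 0.15, 18 of 23 libraries, permutation p = 6.6e-05, camera p = 4.66e-05, estimated p = 0.967). Thermogenic genes rose in 15 of 17 (1.36 ± 0.32, 17 of 23 libraries, permutation p = 0.00072, camera p = 0.00251), and nuclear oxidative phosphorylation genes in 50 of 51 (0.74 ± 0.11, 20 of 23 libraries, permutation p = 6.6e-05, camera p = 6.63e-15), each with estimated p = 0.967. Much of the thermogenic rise lay in part of the libraries, with list means of 5.145 to 5.963 in 3 and 2.65 to 3.855 in the other 4 in Cast (r = 0.909 with log2 Xist, n = 7), and of 4.816 to 5.939 in 4 and 1.492 to 2.665 in the other 4 in PWK (r = 0.952, n = 8), as in WSB. With Xist as a covariate the difference was 1.42 ± 0.218, but 1 shared slope could move it only little, as each strain held libraries low and high in Xist. MHC class II genes fell in 10 of 11 (-1.76 ± 0.14, 23 of 23 libraries, permutation p = 6.6e-05, camera p = 1.84e-08, estimated p = 0.442). Matrix genes fell in 23 of 29 (-0.68 ± 0.0806, 20 of 23 libraries, permutation p = 6.6e-05, camera p = 5.18e-05), and genes of fat mass expansion in 10 of 14 (-1.42 ± 0.15, 21 of 23 libraries, permutation p = 6.6e-05, camera p = 0.00946), each with estimated p = 0.967. Of 11975 called genes, 6164 were higher and 5811 lower.

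For strain origin the strain is the unit, so the medians of all 33 lists were also set beside all 56 splits. In that exact 2-sided test no list passed after adjustment. The 6 lists just named lay farther out than in any other split, for an exact p of 0.0179, the smallest possible, and an adjusted p of 0.0982 in this permutation of strains.

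Examples of these 6 lists were Ehhadh (2.47 ± 0.21), Pdk4 (1.73 ± 0.21) and Acadl (1.51 ± 0.16) up and Cpt1a down (-0.58 ± 0.0978) for oxidation, and Elovl3 (4.12 ± 0.48), Cidea (2.72 ± 0.43) and Ucp1 (3.23 ± 0.68) for thermogenesis. Ucp1 came to 1.79 with Xist as a covariate and lost its call on the variance-stabilised values (1.53). A respiratory example was Uqcrfs1 (1.22 ± 0.13). Class II examples were H2-Eb1 (-4.95 ± 0.20), Ciita (-1.92 ± 0.16) and Cd74 (-1.72 ± 0.14), and matrix examples Col6a1 (-1.21 ± 0.12) and Col6a2 (-1.11 ± 0.12). Leptin (-3.12 ± 0.42) and Nnat (-2.12 ± 0.37) fell and Vegfa rose (1.04 ± 0.0812).

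Camera and permutation called 8 further lists, which lay as far out in at least 1 other split of the strains (adjusted p = 0.131 to 0.241). De novo lipogenesis genes rose in 15 of 20 (0.75 ± 0.16, 19 of 23 libraries, permutation p = 0.000178, camera p = 0.00242, estimated p = 0.967). Acacb (2.03 ± 0.20), Elovl6 (2.02 ± 0.39) and Thrsp (1.71 ± 0.27) were among them. Macrophage markers fell in 20 of 23 (-1.07 ± 0.12, 22 of 23 libraries, permutation p = 6.6e-05, camera p = 3.08e-06, estimated p = 0.967). T and NK cell markers fell in 23 of 24 (-1.16 ± 0.0957, 23 of 23 libraries, permutation p = 6.6e-05, camera p = 4.04e-07, estimated p = 0.709), and B cell markers in 17 of 19 (-1.48 ± 0.19, 21 of 23 libraries, permutation p = 6.6e-05, camera p = 3.8e-05, estimated p = 0.967). Dendritic cell, neutrophil and mast cell markers fell in 13 of 19 (-0.85 ± 0.11, 21 of 23 libraries, permutation p = 6.6e-05, camera p = 0.000562, estimated p = 0.426). Interferon response genes fell in 20 of 30 (-0.76 ± 0.13, 21 of 23 libraries, permutation p = 6.6e-05, camera p = 0.00175), and proliferation genes in 22 of 24 (-0.90 ± 0.14, 19 of 23 libraries, permutation p = 6.6e-05, camera p = 0.00015), each with estimated p = 0.967. Ribosomal protein genes rose in 40 of 52 (0.28 ± 0.0364, 21 of 23 libraries, permutation p = 6.6e-05, camera p = 5.24e-08, estimated p = 0.967), a call that ended without the 41 that share reads.

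Single genes named here parted all 3 wild-derived from all 5 classical strain means by rule, and none was tested with strains as units. Tph2 (-8.95 ± 0.70, adjusted p = 1.7e-16 in edgeR over mice, 23 of 23 libraries) was lower. The mucin-like gene Fcgbp was higher (7.52 ± 0.95, 32 against 0.171 CPM, 14 of 23 libraries), but came to 5.73 without WSB replicate 7 and lost its call without Cast replicate 8 (4.38).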

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

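The counts of genes and lists in other splits of libraries and strains were planned, and the tests of NZO, of transcripts near 0 and of muscle in AJ were chosen after the result was seen. Of 363 groups of libraries 39 (10.7%) held 1 library far from the rest by Dixon's test, where chance gives about 1 in 20, or 18.2 groups. NZO replicate 8 accounted for 15 of them, 129 replicate 9 for 4 and WSB replicate 7 for 3.

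Random splits of the 61 libraries, 25 with the real one, never reached any real count of genes. The real and the highest other count were 16718 and 564 for the strain effect, 3451 and 1051 for 129, 4277 and 539 for AJ, 4899 and 328 for B6, 10451 and 484 for Cast, 4931 and 146 for NOD, 10022 and 154 for NZO, 8105 and 635 for PWK, 9180 and 1690 for WSB, 1823 and 0 for the closest pair in edgeR, and 11260 and 623 for the farthest pair. With strains mixed, this argues only against an absence of strain effects. For lists by camera 24 of 25 splits called at least the real 97, with up to 138, so chance is not excluded for that number. Of the 56 splits of the strains 1, the real one, called as many genes as wild-derived against classical (11975). The next, with B6, NOD and NZO set apart and the wild-derived strains still together, called 10071.

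High immune and low adipocyte transcripts in NZO were weighed first. A lower share of fat cells alone would raise markers of all other cell types. Their medians moved apart, at 1.94 (macrophage), 0.06 (endothelial), 0.02 (progenitor), −0.80 (smooth muscle) and −1.66 (mesothelial, uneven among libraries). Replicate 8 alone is argued against, as without it 36 of 37 genes of both macrophage lists were still called higher. Uneven Xist levels stay open. The fit with Xist (37 of 37) has a shared slope, but both lists rose with Xist only in NZO (r = 0.708 and 0.913). NZO macrophage list means were at least 6.26, with 6.46 in B6 replicate 6 and strain means up to 5.59 elsewhere. A change in number or state of NZO macrophages, with or without fewer fat cells, stays open as a hypothesis.

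The 56 transcripts near 0 in 1 or 2 strains came next, and 39 share reads. A first form of the copy test was void and was replaced after its outcome was seen. Reads moved to a near-identical copy are a candidate explanation where a copy could be tested, since adding the copy restored 10 of 13 genes, and for mt-Co2, where gene and copies came to 0.515 of mt-Cytb in Cast, within its SD of 0.0633 of the lowest other strain. Of 26 genes without a copy 11 had whole estimates in all libraries, so there this stays open. Sequence differences from the reference genome stay open, with 10 genes near 0 in Cast alone, 11 in PWK, 9 in WSB, 2 in NZO and 1 in B6. Of those in 2 strains, Cast had 17, PWK 16 and others at most 3.

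Muscle transcripts in AJ were weighed last. Without the 4 libraries over 300 CPM of muscle markers 2 of 18 were still called higher, but the same markers chose those libraries, so this decides nothing. Most of the rise lay in AJ replicates 3 and 4 (list means 6.18 and 7.04, the rest of AJ at most 1.10), but its source stays open. No biological explanation was tested.

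In NZO replicate 8, far from the other 7 NZO libraries, were Ngp at 560 CPM, Tph2 at 0.973, S100a9 at 818, Lep at 355, Thrsp at 13.5, Gpam at 56.7, Mmp12 at 24.8, Saa3 at 518, Ighm at 2520, Mpo at 229, S100a8 at 571, Mki67 at 135, Gsta3 at 3.34, Nnt at 28.1 and the sum of B cell markers at 4750 CPM. In 129, replicate 9 stood apart with Trim5 at 0.168, Hist2h2aa2 at 0.191, Fcgr1 at 4.76 and Ciita at 18.5 CPM. In AJ, Disp2 had 18 CPM in replicate 3 and Calr 452 CPM in replicate 4. In B6, B cell markers summed to 226 CPM in replicate 3.

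In Cast, 9930111J21Rik1 had 0.0598 CPM and Mx1 44.9 CPM in replicate 5, 9930111J21Rik2 0.374 CPM and Tmem254b 0.935 CPM in replicate 1, Tph2 0.0289 CPM in replicate 8, and liver markers summed to 1360 CPM in replicate 3. In NOD, Hist2h2aa2 had 140 CPM in replicate 7, Thbs1 718 CPM in replicate 6, and replicate 1 a total of 48.4 times 1e+06 counts. In PWK, Cd209a had 0.0554 CPM in replicate 6, Cma1 0.43 CPM in replicate 2, Mpo 9.71 CPM in replicate 1, and muscle markers summed to 133 CPM in replicate 6. In WSB, Zfp738 had 0.0213 CPM, Cfd 1500 CPM and Vegfa 154 CPM in replicate 7, and replicate 4 a total of 19.9 times 1e+06 counts.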

How the results depend on the processing

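Fits without named libraries or genes that share reads, list permutation and estimated correlation with a covariate were chosen after the data were seen. Counts of called genes stayed within 1.5 times their value under the alternatives not named here. With a filter of at least 5 mean CPM, which tests fewer genes, the counts were 10584 for the strain effect, 2068 for 129, 2778 for AJ, 3132 for B6, 6585 for NZO, 5022 for PWK, 7911 for wild-derived against classical strains, 986 for the closest pair and 7282 for the farthest. Without 6 libraries rich in genital duct markers, and so with fewer samples, 1977 genes were called in 129 and 1186 in the closest pair. With a doubling or halving required, which is stricter by construction, the counts were 1150 for 129, 1284 for AJ, 1314 for B6, 3598 for Cast, 1277 for NOD, 3503 for NZO, 2637 for PWK, 2414 for WSB, 2794 for wild-derived against classical, 874 for the closest and 5415 for the farthest pair. Against B6 as reference, which is a contrast of 1 pair, 1941 genes were called in 129, 2177 in AJ and 1920 in NOD.

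Camera called 97 lists, and 0 with an estimated correlation, alone, with Xist as a covariate or with 2 surrogate variables. Raw p lay under 0.05 for 18, 20 and 19 of these, and the lowest adjusted p were 0.394, 0.37 and 0.376. Fry called 130, RLE size factors 97, the replicate block 102, 2 surrogate variables 105, Xist as a covariate 104, the fit without Cast replicates 5 and 6 107, permutation of scores 125, and 94 of 288 were called without genes that share reads, where 10 of the 97 lost their call. The cause of the loss with an estimated correlation was not tested.

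Of named genes, Retnlg in NZO turned from higher (4.22 without Cast replicate 8) to −0.39 (adjusted p = 0.532) without NZO replicate 8, and Mpo in PWK to −0.025 (adjusted p = 0.961) on the variance-stabilised values, where the cause was not tested. Timp1 in Cast turned from 1.97 to −1.435 (adjusted p = 0.0114) without Cast replicates 5 and 6. Besides these reversals, calls lost numbered 29 on the variance-stabilised values, 26 without the duct-rich libraries, 22 without the muscle-rich, 17 without the liver-rich, 13 with the replicate block, 6 with 2 surrogate variables, 7 without Cast replicates 5 and 6, 6 with Xist, 5 without NZO replicate 8, 2 with the stricter filter, 1 with no filter and 1 without Cast replicate 8. DESeq2 lost 0 of 512 and gave no adjusted p for 8, and with RLE size factors and without WSB replicate 7 all 520 kept their call. The share of higher calls, 50.5% to 58.3% at first, fell below 50% on the variance-stabilised values in Cast (48.4%), PWK (49%), WSB (46.7%) and wild-derived strains (48.6%), with the stricter filter in NOD (47.7%) and NZO (49.3%), with 2 surrogate variables in NZO (49.8%), WSB (48.9%) and wild-derived strains (49.9%), with DESeq2 in NZO (49.6%) and WSB (49.2%), without genes that share reads in NZO (49.7%), and without WSB replicate 7 in WSB (49.5%). Libraries with the same replicate number were a little closer, with a median r of 0.108 over 186 pairs against −0.0184 for other pairs, and 21 of 61 were closest to one of their own number, so a relation through that number stays open.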

Other observations

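The test of Ucp1 with Lep was planned, and its repeat with Xist removed was chosen after the result was seen. Permutation, but not camera, called 44 pairs of list and contrast. Circadian clock genes were higher in Cast, with 12 of 18 members up (0.51 ± 0.07, 7 of 7 libraries, permutation p = 6.6e-05), and higher in WSB (0.22 ± 0.07, 8 of 8 libraries, 0.0115), and lower in NZO (-0.20 ± 0.07, 8 of 8 libraries, 0.0179) and NOD (-0.30 ± 0.07, 7 of 8 libraries, 0.00103). Genes of insulin signalling and glucose uptake were lower in NZO, with 11 of 21 members down (-0.23 ± 0.06, 8 of 8 libraries, permutation p = 0.00157), and higher in WSB (0.27 ± 0.06, 8 of 8 libraries, 0.000324). Markers of adipose progenitors and fibroblasts were higher in B6 (0.26 ± 0.09, 5 of 8 libraries, 0.0169) and lower in Cast (-0.36 ± 0.10, 6 of 7 libraries, 0.00191) and WSB (-0.27 ± 0.09, 7 of 8 libraries, 0.0158). Smooth muscle and pericyte markers were lower in NZO (-0.87 ± 0.24, 8 of 8 libraries, permutation p = 0.00416) and higher in B6 (0.64 ± 0.24, 8 of 8 libraries, 0.0285). No contrast was called for endothelial markers by either test.

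Lists of other tissues moved with strain too. Of 18 exocrine pancreas markers only 4 were tested, and these were lower in Cast (-1.85 ± 0.15, 7 of 7 libraries, permutation p = 6.6e-05) and PWK (-0.58 ± 0.14, 8 of 8 libraries, 0.0023) and higher in AJ (0.74 ± 0.15, 7 of 7 libraries, 0.000233), NZO (0.64 ± 0.14, 7 of 8 libraries, 0.000754), B6 (0.62 ± 0.14, 7 of 8 libraries, 0.00106) and NOD (0.40 ± 0.14, 6 of 8 libraries, 0.0214). Red blood cell markers were lower in Cast (-1.25 ± 0.23, 7 of 7 libraries, 6.6e-05), and less so in 129, AJ and B6, and higher in NZO (0.79 ± 0.22, 8 of 8 libraries, 0.00274). Mammary and skin epithelial markers, 7 of 16 of them tested, were higher in 129 (1.11 ± 0.46, 5 of 7 libraries, 0.0413), with list means of 1.361 to 2.643 in replicates 6, 7 and 9, which held 437 to 1220 CPM of genital duct markers, against -2.031 to -0.2682 in the other 4, and lower in WSB (-1.23 ± 0.43, 7 of 8 libraries, 0.0179). Duct markers summed to 405 ± 562 CPM in 129 (SD, n = 7) and 414 ± 1020 CPM in NOD (SD, n = 8). Mitochondrially encoded transcripts took 4.29 ± 0.653% of counts in NZO and 9.25 ± 5.31% in PWK (SD, n = 8 each), with 11.7 to 16.9% in 4 PWK libraries and 3.86 to 5.06% in the other 4. Xist ranged from 0.0253 to 744 CPM over the 61 libraries.

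Libraries with more Ucp1 were predicted to hold less Lep within strains. The mean within-strain rho was −0.311 and the mean r of log2 levels −0.335 (permutation p = 0.0237 and 0.0148). Both were negative in 6 of 8 strains, but not in Cast (r = 0.824) and NZO (0.928). There Cast replicates 5 and 6 and NZO replicate 8 were lowest in both genes. Without the 2 libraries farthest from the median Ucp1 per strain the means were −0.425 and −0.552. With log2 Xist removed the mean r was 0.0227 (permutation p = 0.87), from -0.735 in AJ to 0.937 in NZO and negative in 4 of 8 strains. This decides nothing, and a relation through Xist stays open.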
